A study of Mus musculus with 4 samples.

How the data were processed

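RNA was measured by sequencing in otic vesicles, the epithelial sacs from which the inner ear develops, of C57/BL6 mouse embryos at embryonic day 11.5. There were 2 wild-type libraries (WT 1 and WT 2) and 2 libraries of Meis2 mutants (KO 1 and KO 2), with groups and replicate numbers taken from the sample titles. Per the labels' protocols, RNA was extracted with a column kit for small samples and sequenced on an Illumina instrument. How many embryos or vesicles went into a library is not given in the sources used here. The p-values of single genes therefore measure the spread between these libraries, which may be partly technical.

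The authors deposited gene-level TPM (transcript abundances scaled to a fixed total per library). The submitters' processing notes name Salmon 0.9.1 and the genome build GRCm38; the annotation release and the way transcripts were summed per gene are not given in the sources used here. The table listed 34866 genes, and each library summed to 1000000 TPM. Multiplied by 4, all nonzero values of WT 1, WT 2 and KO 1 were whole multiples of the smallest printed step, and those of KO 2 were when multiplied by 3 (tolerance 0.02 of a step). They therefore look like means of 4 and of 3 values, and whether these were runs or lanes is not stated. TPM keeps no depth, so the depth of each library is unknown and no counting interval is given. Between 20829 and 21685 genes were above 0 per library, and 10520 genes were at 0 in all 4. Coding genes made up 21782 of the rows, and most of the others were pseudogenes. A pseudogene that is nearly identical to a coding gene can take part of its reads, so values of such pairs are uncertain.

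Gene IDs were matched by number to the GENCODE M21 annotation of GRCm38, which named 34582 of them (32574 with the same version) and gave the coordinates; 284 had no symbol. Genes with a mean of at least 1 TPM over the 4 libraries were tested (14496 genes, 13503 of them coding and 924 pseudogenes). The test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with genotype as the only term, a mean-variance trend in the moderated variance, two-sided p-values and Benjamini-Hochberg adjustment, with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, KO minus WT, and understate changes of low genes. Values are given as mean ± SD of the 2 libraries, and a fold change with its standard error (SE). No exact test of 2 libraries against 2 can give a two-sided p below 0.333.

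Before the data were examined, 31 gene lists were fixed, covering otic epithelium and its patterning, neurons, other cell types, signalling pathways and RNA quality. The 28 lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. At the preset correlation, camera compares the members' statistics with those of all other genes. Its p-values treat genes nearly as replicates and do not measure the spread between libraries. The Hox list and the Y-linked list had 4 tested members each and are given as values; the list of Xist and Tsix was not analysed here. The named genes follow a rule fixed at the same time. It takes Meis2, then up to 6 genes per direction with the smallest p among those with a log2 change of at least 1 and no overlap between groups where too few pass the threshold, then the 2 members of each list with the smallest p (1 for other cell types). Predicted genes and pseudogenes are named by it only if among the first 5 of a direction. Other genes named in the text were chosen after their values were seen.

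The fit was tested on simulated data: 20 simulations of KO against WT with 14496 genes and 200 changed genes each, with independent noise drawn from the variance distribution that limma estimated. It called 42.6% of genes with a log2 change of 1, 76.6% of those with 2 and 89.1% of those with 3, with a mean of 7.95 false calls. A list moved by 0.4 was called in 20 of 20 simulations at the preset correlation and in 0 of 20 with an estimated one. A first version, with noise from each gene's own moderated variance, called more of the changed genes and was replaced because its variances were too even. The simulations held no differences between libraries shared across genes.

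The alternatives were other pseudocounts (0.1 and 5 TPM), no filter or a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, leaving out mitochondrial, globin and Y-linked genes, other moderation of the variance, a replicate block, other list tests, and leaving out each library. A fit of protein-coding genes only, camera with a mean-variance trend, the ectoderm list without keratins 8, 18 and 19, and list means over the genes tested with all 4 libraries were added after the data were seen.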

Results

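Transcripts were measured in otic vesicles of wild-type and Meis2 mutant mouse embryos at embryonic day 11.5, with 2 libraries per genotype, to find genes whose level depends on Meis2. Meis2 encodes a homeodomain transcription factor of the TALE class. Values are gene-level TPM, whose depth is unknown.

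Meis2 itself (ENSMUSG00000027210.20, chromosome 2, 115863064 to 116065839, GRCm38) was present in all 4 libraries. It was at 79.0 TPM in WT 1, 88.7 in WT 2, 73.2 in KO 1 and 76.6 in KO 2. The log2 difference was -0.16 (SE 0.087; limma adjusted p = 1.00). The deleted part of the gene is not given in the sources used here, and a gene-level value cannot show whether an exon is missing, so this value does not check the genotype labels. Of the 18 TALE homeobox genes tested, 10 were higher and 8 lower in KO, and the list as a group did not pass its test (camera adjusted p = 0.91). Pbx3, whose product binds DNA together with Meis proteins, was at 43.2 ± 1.96 TPM (SD, n = 2) in WT and 48.4 ± 1.53 TPM (SD, n = 2) in KO.

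In the comparison of KO with WT, the gene with the smallest p was Fst, which encodes follistatin, a secreted inhibitor of activin. Fst (ENSMUSG00000021765.8, chromosome 13, 114452290 to 114458951) stood at 14.5 ± 0.445 TPM (SD, n = 2) in WT and 4.81 ± 0.594 TPM (SD, n = 2) in KO, a log2 difference of -1.42 (SE 0.14). Aldh1a2 (ENSMUSG00000013584.5, chromosome 9, 71215789 to 71296243), a retinoic acid synthesizing enzyme, was at 8.90 ± 0.477 TPM in WT and 3.14 ± 0.352 TPM in KO (SD, n = 2 each), a difference of -1.26 (SE 0.15). Acta2 (ENSMUSG00000035783.8, chromosome 19, 34241090 to 34255590), the actin of smooth muscle, was at 10.5 ± 0.707 and 2.89 ± 0.998 TPM (SD, n = 2 each), a difference of -1.58 (SE 0.23). In the other direction, Otoa (ENSMUSG00000034990.15, chromosome 7, 121081650 to 121163097), which encodes the inner ear matrix protein otoancorin, was at 1.93 ± 0.255 TPM in WT and 5.55 ± 0.312 TPM in KO (SD, n = 2 each), a difference of 1.16 (SE 0.18). Zfp972, a zinc finger gene, differed by 1.28 (SE 0.22). The rule that named these 5 genes required that WT and KO did not overlap.

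None of these genes passed the threshold over all genes tested. With limma, 0 of 14496 genes passed, 0 higher and 0 lower, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 507 genes, 303 higher and 204 lower, where chance alone would give 725; without WT 2 there were 336. WT and KO did not overlap for 29.8% of genes, against 33.3% by chance. Split by replicate number, the same libraries gave 1982 genes at an unadjusted limma p under 0.05. The fit by genotype leaves that difference in its spread, so counts below chance do not show that no gene differs. The text the authors gave with the series states 18 genes at a false discovery rate below 0.05; their names and the test behind them are not given in the sources used here. On simulated libraries the same fit called 42.6% of genes with a log2 change of 1. Each simulation held 200 changed genes and no differences between libraries shared across genes, so this share need not hold for the real libraries. The genes called without KO 1 or without KO 2 carried the Gm numbers of predicted genes, apart from BC002163 and Rpl35a-ps6. Among genes with a log2 difference of at least 1 and no overlap, 43 were higher and 54 lower, of which 13 and 15 were coding. The other genes of this kind with the smallest p were pseudogenes. Gm10263, Gm10046, Gm10042 and Gm44638 were higher and Gm12039, Gm48576 and Gm28911 lower, and copies of this kind can share reads with other genes.

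**Figure D1:**
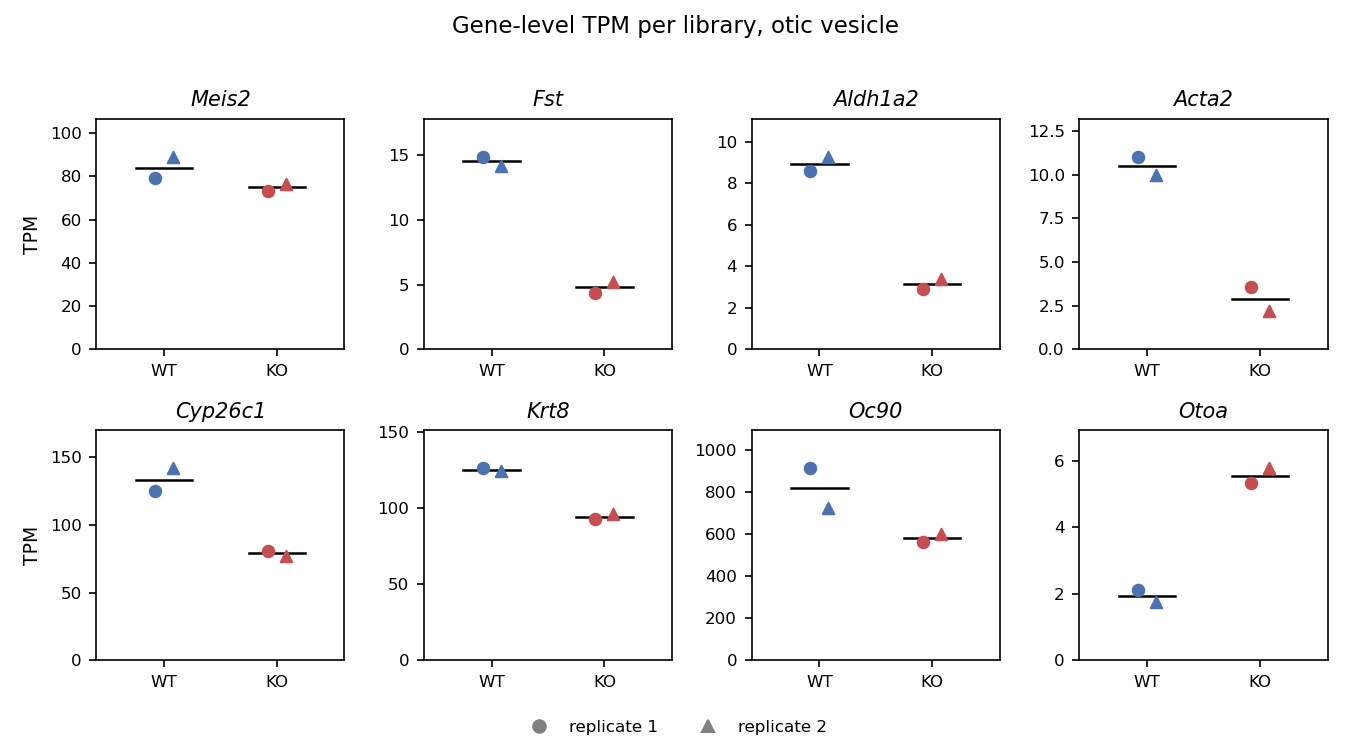
TPM (y axis, linear, starting at 0) of 8 genes in each library; circles are replicate 1, triangles replicate 2 and black lines the mean of the 2 libraries of a genotype. Fst lies at 14.9 and 14.2 TPM in WT and 4.39 and 5.24 TPM in KO, while Meis2 lies between 73.2 and 88.7 TPM in all 4.

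Genes of the otic epithelium stood lower in KO as a group: 16 of 20 tested identity genes were lower, with a mean log2 difference of -0.15 (camera adjusted p = 3.6e-05; adjusted p = 0.82 with an estimated correlation). The test with an estimated correlation called a simulated list moved by 0.4 in 0 of 20 simulations. Its p-values, here and below, therefore cannot count against a list. Sall4, a zinc finger transcription factor, was at 15.5 ± 1.36 TPM in WT and 9.42 ± 0.670 TPM in KO (SD, n = 2 each). Oc90, the main protein of the otoconial matrix, was at 818 ± 133 and 582 ± 28.5 TPM (SD, n = 2 each), a log2 difference of -0.48 that was -0.32 without WT 1. Among ventral, cochlear patterning genes 11 of 18 were lower (mean -0.12, adjusted p = 0.012; adjusted p = 0.82 with an estimated correlation), including the transcription factors Gata3 (-0.36, SE 0.11) and Otx2 (-0.52, SE 0.17; -0.32 without KO 1). Among dorsal, vestibular patterning genes 10 of 15 were lower (mean -0.08, adjusted p = 0.031; adjusted p = 0.82 with an estimated correlation), with Gbx2 at -0.62 (SE 0.26) and Ntn1 at -0.46 (SE 0.20). Without KO 2 Gbx2 was at -0.27 and Ntn1 at -0.22, and without KO 1 they were at -0.97 and -0.69. No member of these 3 lists passed the threshold over all genes, and 0 passed when adjusted over the list alone. Between the replicate numbers the ventral list differed by more, with a mean of 0.22 for number 2 minus number 1 (camera adjusted p = 0.024). Relative to the mean of all libraries, the ventral list was higher in KO 2 (0.08) than in WT 1 (-0.02). The dorsal list was higher in KO 1 (0.07) than in WT 1 (0.05) or WT 2 (0.03). Of these 3 lists, only the identity list did not overlap between the genotypes. The identity mean was -0.08 without KO 1, still called; the ventral call was lost without WT 2 (mean -0.03) and without KO 1 (mean 0.02), and its mean was -0.20 without WT 1 and -0.26 without KO 2. The dorsal call was lost without WT 1, WT 2 or KO 2, with a mean of 0.03 without KO 2 and -0.20 without KO 1, and also with no filter and with quantile normalization.

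The surface ectoderm and epidermis list was also lower, in 7 of 9 tested members (mean -0.26, camera adjusted p = 3.6e-05; adjusted p = 0.82 with an estimated correlation). Its 3 calls adjusted over the list alone were Krt8, Krt18 and Krt19, the last named after its values were seen. These encode keratins of simple epithelia in general, not of epidermis alone. Krt8 was at 125 ± 1.23 TPM in WT and 94.5 ± 2.25 TPM in KO, and Krt18 at 133 ± 1.57 and 107 ± 0.693 TPM (SD, n = 2 each). Without these 3 keratins, an alternative set after seeing the data, the mean of the other 6 was -0.21 (camera adjusted p = 0.047; unadjusted camera p = 0.12 with an estimated correlation). Over all genes tested, 0 of the 9 passed. Epidermal genes below the filter were higher in KO 1 alone: Krt5 was at 3.28 TPM there and at most 0.15 in the other libraries, and Trp63 at 1.29 and at most 0.22. With no filter, which adds these genes, the list mean was -0.03. Without KO 2 the filter admits Krt5, and the list was not called (mean 0.04, adjusted p = 0.099); over the same 9 members its mean was -0.18 (adjusted p = 0.0040).

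Within the retinoic acid pathway 11 of 17 genes were lower and 6 higher (mean -0.07, camera adjusted p = 0.022; adjusted p = 0.82 with an estimated correlation). Adjusted over the list alone 2 genes passed, against 0 over all genes. They were Aldh1a2, described above, and Cyp26c1, which encodes a retinoic acid degrading enzyme. Cyp26c1 (ENSMUSG00000062432.4, chromosome 19, 37685581 to 37693398) was at 133 ± 11.8 TPM in WT and 79.0 ± 2.69 TPM in KO (SD, n = 2 each), a log2 difference of -0.74 (SE 0.089). Members named after their values were seen lay on the other side, with the receptor gene Rarb at 0.62 (SE 0.20) and the synthesizing enzyme Aldh1a3 at 0.68 (SE 0.32). The Aldh1a3 difference was 0.14 between the libraries numbered 1 and 1.21 between those numbered 2. The list call was lost without WT 1 (mean -0.02), WT 2 (-0.12) or KO 2 (-0.04) and with quantile normalization. The genotypes overlapped: relative to the mean of all libraries, the list was higher in KO 1 (-0.0062) than in WT 2 (-0.018).

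Periotic mesenchyme genes, which mark the tissue around the vesicle, were higher in KO in 17 of 18 tested members (mean 0.33, camera adjusted p = 0.012; adjusted p = 0.82 with an estimated correlation). Lum, which encodes the matrix proteoglycan lumican, was at 19.99 ± 6.01 TPM in WT and 36.9 ± 7.46 TPM in KO (SD, n = 2 each), a log2 difference of 0.87 that was 0.57 without WT 2. The mesenchyme mean was 0.39 between KO 1 and WT 1 and 0.26 between KO 2 and WT 2, and 0 of the 18 passed over all genes or adjusted over the list alone. The genotypes overlapped, since KO 2 lay below WT 1. Relative to the mean of all libraries, the list lay at -0.0042 in WT 1, -0.32 in WT 2, 0.38 in KO 1 and -0.058 in KO 2. Between the replicate numbers the same list differed by more, with a mean of -0.38 for number 2 minus number 1 (camera adjusted p = 2.3e-05). The list was not called without WT 2 (mean 0.17) or without KO 1 (mean 0.11), and without KO 2 its mean was 0.55. Mitochondrially encoded genes were higher in 12 of 13 (mean 0.19, adjusted p = 0.0055; adjusted p = 0.82 with an estimated correlation), with a mean of 0.03 between the libraries numbered 1 and 0.35 between those numbered 2. For mt-Cytb the log2 difference was 0.29 (SE 0.11; 0.19 without KO 2), and the list was not called without WT 2 (mean 0.13) or without KO 2 (mean 0.09), while without KO 1 its mean was 0.29.

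The preset correlation called 7 of 28 lists between the genotypes, but it also called 5 lists when the same libraries were split by replicate number, and 8 when WT 2 and KO 1 were set against WT 1 and KO 2. That last split also followed Y-linked transcripts: Eif2s3y was at 13.4 and 58.1 TPM in WT 1 and KO 2, and at most 0.17 elsewhere. Its 8 calls therefore do not measure chance alone. An estimated correlation called 0 lists in the genotype comparison, and fry called 0 in one direction and 1, surface ectoderm, in either direction. A simulated list moved by 0.4 was called in 0 of 20 simulations with an estimated correlation. Between the replicate numbers the neuron list, with a mean of 1.03, was also not called by it (camera adjusted p = 0.68). Its 0 calls therefore cannot count against the lists called at the preset correlation. The preset p-values rest on genes, not on the spread between libraries, and assume a correlation of 0.01. The estimated correlation was 0.16 for otic epithelium, 0.14 for dorsal otic, 0.46 for ventral otic, 0.56 for mesenchyme and 0.58 for mitochondrial genes. It was -0.03 for ectoderm and -0.05 for retinoic acid. Where genes correlate above the preset, its p-values are too small. The 20 simulations held independent noise.

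The other lists did not pass in the fit of all 4 libraries with a mean of at least 1 TPM. With a mean of at least 5 TPM, 10 lists passed, adding endothelium (adjusted p = 0.039), Wnt targets (0.042) and glycolysis and hypoxia (0.025), and with no filter cartilage passed (0.042). With a library left out, matrix secretions passed without WT 1, glycolysis without WT 2, BMP targets without KO 1, skeletal muscle without WT 1 or KO 2, and cartilage, hindbrain, endothelium and macrophages without KO 2. Among matrix secretions of the inner ear 5 of 6 genes were higher (mean 0.34, camera adjusted p = 0.080), and Otoa was the 1 call adjusted over the list alone. The lower gene was Oc90, the most abundant of the 6, at 818 TPM in WT and 582 TPM in KO. The matrix mean was 0.50 without WT 1 and 0.17 without WT 2. Prosensory and hair cell genes had a mean of -0.03 (8 of 13 lower, adjusted p = 0.35), from -0.17 without KO 2 to 0.12 without KO 1, with Cdh4 at 0.39 (SE 0.19) and Myo6 at 0.31 (SE 0.16). The neuron list had 19 of 24 members higher (mean 0.11, adjusted p = 0.88), with a mean of -0.27 between KO 1 and WT 1 and 0.50 between KO 2 and WT 2. It was called higher without KO 1 (mean 0.82, adjusted p = 2.8e-08) and lower without KO 2 (mean -0.59, adjusted p = 3.4e-08). The neuronal filament gene Prph was at 0.51 (SE 0.15) and Nhlh2 at 0.47 (SE 0.51). Cartilage genes were higher in 10 of 13 (mean 0.14, adjusted p = 0.080), from 0.02 without KO 1 to 0.21 without KO 2, with Col2a1 at 0.24 (SE 0.071) and Cnmd at -0.35 (SE 0.12).

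Lists of other cell types moved apart between the numbered libraries. Erythroid genes were lower in 12 of 14 (mean -0.15), with a mean of 0.36 between the libraries numbered 1 and -0.67 between those numbered 2 (adjusted p = 0.13 over all 4), and the list was called lower without WT 1 (mean -0.75) and higher without WT 2 (mean 0.45). Macrophage genes were higher in 9 of 12 (mean 0.17, adjusted p = 0.21), with 0.51 and -0.18 in the numbers and from -0.05 without KO 1 to 0.39 without KO 2. Endothelial genes were higher in 11 of 14 (mean 0.12, adjusted p = 0.080), with 0.31 and -0.06 in the numbers and from -0.02 without KO 1 to 0.26 without KO 2. Hbb-bs, 1 of the 2 erythroid genes that were higher, differed by 0.59 (SE 0.18), Lyz2 by 0.33 (SE 0.17) and Emcn by 0.33 (SE 0.097). Neural crest and glia genes had a mean of 0.10 (adjusted p = 0.51), from 0.03 without KO 1 to 0.16 without KO 2, with Mia at 0.57 (SE 0.14). Hindbrain genes had 0.16 (adjusted p = 0.51), with Zic1 at 0.60 (SE 0.17). The hindbrain mean was -0.10 without KO 1, -0.06 without WT 2, 0.39 without WT 1 and 0.54 without KO 2. All 5 tested skeletal muscle genes were lower (mean -0.17, adjusted p = 0.080), with Mylpf at -0.36 (SE 0.16). The muscle mean was 0.01 without KO 1, -0.08 without WT 2, -0.26 without WT 1 and -0.35 without KO 2. Y-linked genes also differed between libraries: Eif2s3y was at 13.4 TPM in WT 1, 0.17 in WT 2 and 58.1 in KO 2, and listed at 0 in KO 1. Kdm5d was at 4.69, 0.73, 20.2 and 0.57 TPM in WT 1, WT 2, KO 2 and KO 1. The 4 tested Hox genes had a mean of 0.14, with 0.59 between the libraries numbered 1 and -0.32 between those numbered 2. Hoxb3 differed by 0.28 (SE 0.26).

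**Figure D2:**
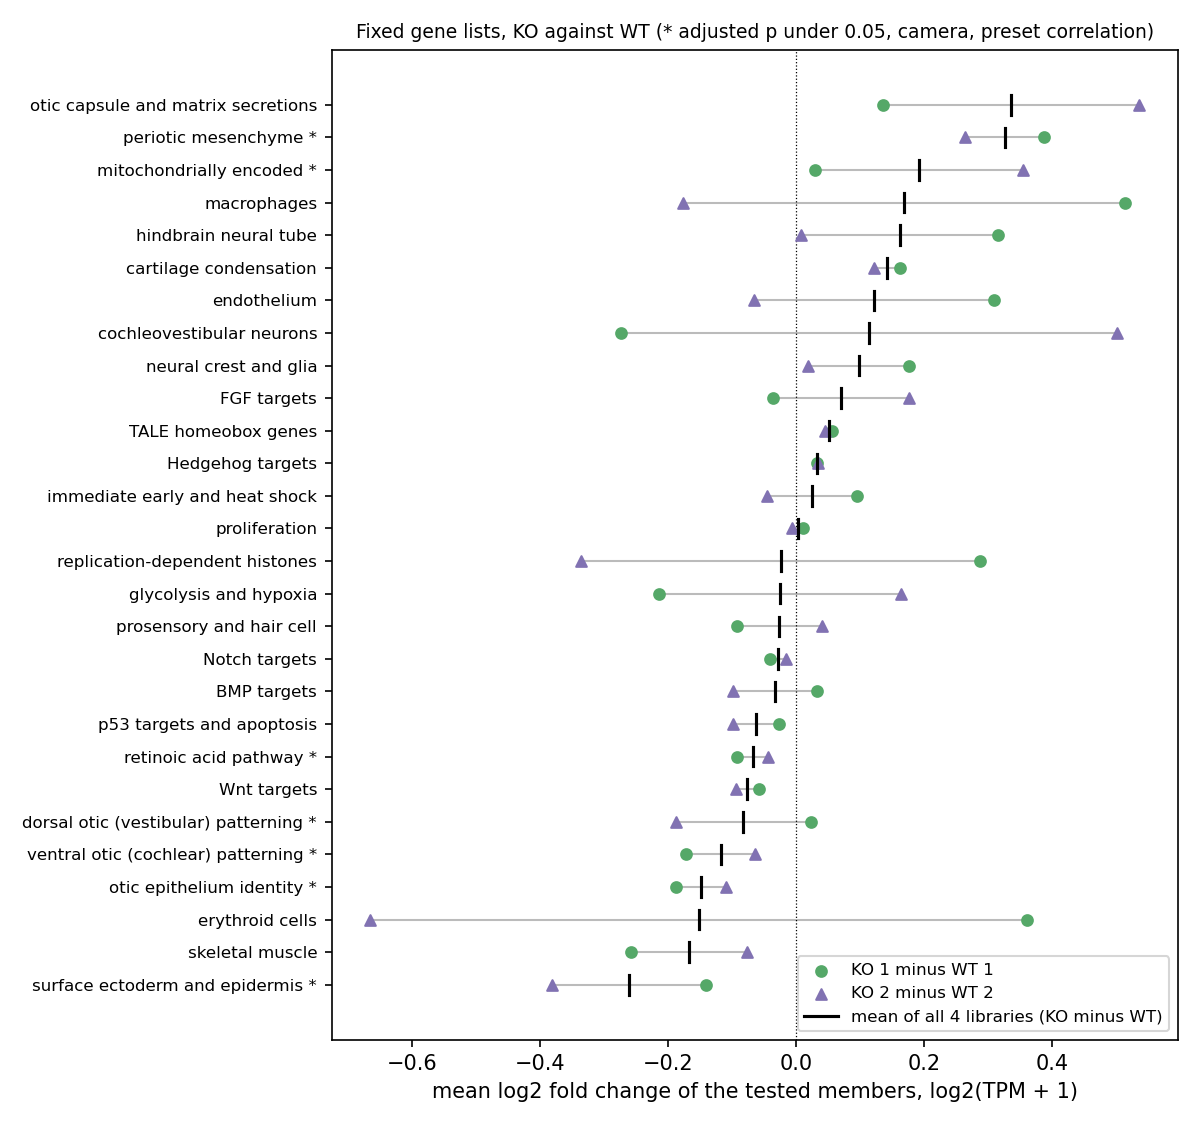
Mean log2 fold change of the tested members (x axis, on log2(TPM + 1)) of the 28 tested lists; circles are KO 1 minus WT 1, triangles KO 2 minus WT 2, black bars the difference between the genotype means, and stars the 7 lists with a camera adjusted p under 0.05. Periotic mesenchyme lies above 0 in both numbers (0.39 and 0.26), while neurons (-0.27 and 0.50) and erythroid cells (0.36 and -0.67) change sides. The numbers are not treated as pairs, and the mesenchyme mean of KO 2 was below that of WT 1.

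Apart from the retinoic acid pathway, described above, no signalling list passed its test with all 4 libraries and a mean of at least 1 TPM. Wnt targets had a mean of -0.08 (adjusted p = 0.080), with Tcf7 at -0.30 (SE 0.097) and Rnf43 at -0.53 (SE 0.21). BMP targets had -0.03 (adjusted p = 0.080), from -0.13 without KO 1 to 0.06 without KO 2, with Smad7 at -0.25 (SE 0.11) and Bmper at -0.36 (SE 0.17). FGF targets had 0.07 (adjusted p = 0.57), from 0.0040 without WT 2 to 0.14 without WT 1, with Etv4 at 0.30 (SE 0.18) and Etv1 at 0.24 (SE 0.19). Notch targets had -0.03 (adjusted p = 0.14), from -0.14 without KO 2 to 0.08 without KO 1, with Jag2 at 0.47 (SE 0.17) and Hey1 at -0.17 (SE 0.095). Hedgehog targets had a mean of 0.03 and a median of -0.00 (adjusted p = 0.64), from -0.0036 without WT 2 to 0.07 without WT 1, with Boc at 0.43 (SE 0.14) and Ptch1 at -0.21 (SE 0.13). Hedgehog targets, proliferation genes and immediate early genes were the 3 lists whose mean, median and test differed in sign. Camera sets a list against all other genes, and the median log2 difference of all genes tested was 0.035. A slightly positive list mean can therefore still be tested as lower.

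Proliferation genes had a mean of 0.0025 over 25 members (adjusted p = 0.51), from -0.02 without KO 1 to 0.02 without KO 2, with Pcna at -0.15 (SE 0.091) and Mcm2 at -0.10 (SE 0.066). The p53 target list had a mean of -0.06 (adjusted p = 0.14), from -0.12 without WT 1 to -0.0047 without WT 2, with the cell cycle inhibitor gene Cdkn1a at -0.52 (SE 0.17) and Bbc3 at -0.33 (SE 0.12). Glycolysis and hypoxia genes had -0.03 (adjusted p = 0.17), from -0.15 without WT 2 to 0.10 without WT 1, with Car9 at 0.51 (SE 0.18) and Pfkp at 0.51 (SE 0.19). Immediate early and heat shock genes had 0.03 (adjusted p = 0.88), from -0.04 without WT 1 to 0.10 without WT 2, with Jun at 0.22 (SE 0.091) and Ier2 at -0.11 (SE 0.067). Histone genes had -0.02 (adjusted p = 0.74), from -0.24 without KO 1 to 0.20 without KO 2, with Hist1h2ab at 0.70 (SE 0.33) and Hist1h3c at 0.22 (SE 0.14). Of the 60 genes other than Meis2 that the rule named, 30 changed sign or moved by over 1.5 times when 1 library was left out. Among them were Hoxb3, Cdh4, Myo6, Cnmd, Zic1, Hbb-bs, Lyz2, Mylpf, Rnf43, Ptch1, Etv4, Bmper, Hey1, Pcna, Cdkn1a, Car9, Pfkp, Hist1h2ab and Hist1h3c, besides Nhlh2, Etv1 and Kdm5d, which changed sign.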

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

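The fit of coding genes only, camera with a mean-variance trend, the ectoderm list without 3 keratins and list means over the genes tested with all 4 libraries were chosen after seeing the data. The count of 0 genes past the threshold was the same under every alternative that kept all 4 libraries, with limma's smallest adjusted p between 0.41 and 1.00, and ranged from 0 to 10 when a library was left out (0 to 4 higher, 0 to 6 lower; 336 to 735 at an unadjusted p under 0.05). Where 1 library of a genotype is left, it is assumed to vary like the other genotype's. Meis2 stayed lower and not called throughout, from -0.24 to -0.08. Calls adjusted over each list alone numbered 6, with 3 for eBayes without a trend and 3 to 17 without a library. Lists past the threshold numbered 7, with 10 at a mean of at least 5 TPM, 4 to 9 without a library, 0 with an estimated correlation and 0 with fry in one direction. The count with an estimated correlation decides nothing, since it called a simulated list moved by 0.4 in 0 of 20 simulations. Other moderation of the variance does not enter camera. The ectoderm mean was -0.03 with no filter. Quantile normalization ended the calls of the dorsal otic and retinoic acid lists, and no filter that of dorsal otic. Otic epithelium kept its call in 4 of 4 fits without a library. List means without a library ranged from -0.256 to 0.01999 for ventral otic, -0.196 to 0.0319 for dorsal otic, 0.105 to 0.548 for mesenchyme, -0.344 to 0.0352 for ectoderm (-0.344 to -0.179 over the same 9 members, called each time), -0.215 to -0.082 for otic epithelium, -0.119 to -0.015 for retinoic acid and 0.095 to 0.289 for mitochondrial genes. Without KO 2 Krt5 enters the ectoderm list, and the mean was 0.04, against -0.18 over the same 9 members. It also enters without WT 1 (-0.16, against -0.30) and without WT 2 (-0.11, against -0.22). Causes of the other changes were not tested. Of 60 named genes other than Meis2, 3 changed sign: Etv1 (-0.0032 to 0.49), Nhlh2 (-0.18 to 1.13) and Kdm5d (-0.997 to 2.75), each when a library was left out. The replicate block gave 0 genes, 1178 at an unadjusted p under 0.05 against 507 without it, 20 calls adjusted over each list alone and 4 lists, ending the dorsal otic, retinoic acid and mitochondrial calls. Same-numbered libraries deviated together, with a correlation across genes of 0.42, but with 2 pairs and no label tying the numbers they are not treated as paired. TPM keeps no depth, so what depth limits cannot be given.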

Other observations

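The tests in this part were chosen after their results were seen, except the correlation among protein-coding genes. Of 3 gene families looked at after the values were seen, all 5 tested Zic genes were higher in KO in both numbers, with a mean log2 difference of 0.55. They encode transcription factors of the dorsal neural tube and its derivatives. The numbers are not treated as pairs, and the Zic2 values of WT and KO overlapped. The hindbrain list, which holds Zic1 and Zic2, had a mean of -0.60 for number 2 minus number 1, against 0.16 between the genotypes. Zic4 was at 18.2 TPM in WT and 34.9 TPM in KO. Of 32 collagen genes 26 were higher, with a mean of 0.23 (24 with median-of-ratios scaling and 23 with quantile normalization). Of 22 gamma protocadherins 12 were higher, with a mean of 0.07, and 10 with quantile normalization. No test is given for these families, since they were picked by their values. Tgfb2, a TGF-beta ligand, was at 26.2 TPM in WT and 42.4 in KO, and Myc at 18.2 and 9.65 TPM; neither passed limma's threshold (adjusted p = 1.00).

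Epithelial lists stood lower and mesenchyme higher in KO. A smaller share of epithelium would raise all other cell types alike, and more mesenchyme alone would lower all other lists alike. The highest and lowest list means lay 0.479 apart between the genotypes for the first and 0.321 for the second, while other splits of the same 4 libraries gave gaps of up to 1.41 and 1.13. Splits of 4 libraries are too few for a gap of any size to decide. These gaps therefore test neither explanation, and both stay open. Tissue amounts that differ between dissections by chance cannot be told apart from an effect of Meis2, since 2 libraries against 2 cannot give an exact p below 0.333. An effect of Meis2 on these genes stays open and untested.

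Libraries split by replicate number more than by genotype: limma called 24 genes between the numbers and 0 between the genotypes, or 6 and 0 when only coding genes were fitted. Of the 24, 70.8% were pseudogenes, against 6.37% of genes tested (Fisher's exact p = 9.3e-16), consistent with reads divided differently between coding genes and their copies; Rps13-ps1 was at 1235 and 1212 TPM in WT 1 and KO 1 and listed at 0 in WT 2 and KO 2, while Rps13 itself was at 646 and 618 TPM in the former and 1587 and 1412 in the latter, and with its copies summed to 1605 to 1882 TPM. Since coding genes that share reads with copies move with them, the correlations among coding genes (lowest same-numbered minus highest same-genotype, -0.00018) do not decide whether copies are the whole of it. Neuron genes were part of the split, being higher in number 2 by 0.640 in WT and 1.41 in KO, while same-numbered libraries differed by at most 0.50. Copies of neuron genes were not summed with them, so these values do not test whether copies account for the neuron part. More neuronal tissue in the libraries numbered 2 may account for the neuron part, but this rests on the same values and was not tested apart from them. The labels name no batch.

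The mitochondrial list stood higher in KO. Reads shifted from nuclear copies on chromosome 1 would leave the sum of both alike, but it differed by 0.307 (log2) between KO 2 and WT 2 and by 0.05 between KO 1 and WT 1. The list mean of 0.354 between KO 2 and WT 2, against 0.03 for number 1, is consistent with a difference of 1 library pair. Whether genotype has a part in it was not tested.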
